A study of Mus musculus with 2 samples.

How the data were processed

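Single-cell RNA sequencing of lung tissue from 1 wild-type and 1 Traf5 knockout mouse gave 1 library per group, and the groups are taken from the genotype in the labels. The deposited matrices hold raw UMI counts per gene and cell barcode, made by the authors with Cell Ranger and not normalized. The labels name Cell Ranger 6.0.1 and the mouse build mm10, while the file headers name version 7.1.0. Whether reads in introns were counted is not stated, so the counts cannot be split into spliced and unspliced RNA. Each matrix lists 27998 genes, and the lowest barcode total is 500 UMIs in each, so cells had been called before deposit. An annotation of cells by the authors was not used here. The gene list holds no immunoglobulin or T cell receptor genes under the names that were fixed, so these were not analysed, and Pydc4, Gucy1a3 and Gucy1b3 are the names in the files for the list members Ifi213, Gucy1a1 and Gucy1b1. Positions of Traf5 and its neighbours come from the GENCODE annotation of the same build.

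Cells were kept with at least 500 UMIs, at least 250 genes and at most 20% of UMIs from mitochondrial genes. This left 9443 of 9594 wild-type and 12824 of 13019 knockout barcodes. Doublets were called in each library with scrublet in scanpy 1.11.5 at its automatic threshold (scores of 0.2338 and 0.3089), with an expected rate of 0.8% per 1000 barcodes, or 7.68% and 10.4%. It marked 437 and 579 barcodes, which were removed. These are 4.63% and 4.52% of the barcodes that passed the filters, below the expected rates. Doublets may therefore remain, with the wider gap to the expected rate in the knockout library. The kept cells held 62610625 and 101292539 UMIs. Median mitochondrial shares were 1.97% and 2.19%.

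The libraries were integrated and clustered with Seurat 5.3.0 in R 4.3.3, since the design text says that the authors used its functions, with 2000 variable genes, 30 components and resolution 0.8. Of 243 marker genes fixed before the data were examined, 237 are in the gene list of the files. A cluster took the name of the cell type with the highest mean log2 marker score if that was at least 1.5, at least 3 markers were detected (a UMI in at least 10% of cells and 2-fold enrichment), and its 10 leading genes did not go against the name. The limits of this scoring were set after the data were seen. Of 35 clusters, 30 were named and 5 were not, giving 25 classes, each called by its type and "-like". Names are rebuilt and can differ from those of the study.

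UMIs were summed per library and class, and CPM is relative to the sum of all genes in that class. Ratios have exact conditional binomial intervals, CPM exact Poisson intervals and shares exact binomial (Clopper-Pearson) intervals, all at 95% and covering counting error only. A CPM from 0 UMIs is limited by a floor of 3 counts, and a share of 0 cells by the upper bound of its interval. The intervals were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures with matplotlib 3.10.9. A gene was measured in a class with at least 20 UMIs over both libraries. Classes with at least 100 cells in each library were compared gene by gene, and the mural class was added below that limit after the data were seen, which made 16 classes. Smooth muscle cells and pericytes did not separate, so their lists were read in the mural class, and the dendritic cell types were read as 1 class. With 1 library per group no test was run, and no p-value was made from cells.

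Named genes followed a rule fixed before the data were examined. In each class with at least 200 cells per library it takes the 6 genes per direction with the interval bound farthest from 1. They need a ratio beyond 1.5-fold, at least 100 UMIs and a UMI in at least 5% of cells in the higher library, and a CPM of at least 20% of the highest class there. In each list it takes the 4 members with the largest ratio either way and at least 50 UMIs. Markers of other classes, Xist, haemoglobin, mitochondrial and ribosomal protein genes and unnamed gene models were left out. The text names part of the genes that the rule takes. The part named, the Traf5 values of ciliated cell-like cells, Kcnh1, Nek2, Apoe, Gucy1a3 outside endothelium-like cells and the genes of the closing part outside the rule were chosen after their values were seen. Of 40 fixed gene lists, 37 could be measured in a planned class. The median log2 ratio of a list was set against 10000 random lists matched on size and expression.

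Simulated data were Poisson counts at the depth of each library, drawn from the pooled counts of a class with known folds put into 200 genes. There the interval held the true ratio for 95.8% of 11233 unchanged genes in T cell-like cells and 95.5% of 12182 in endothelium-like cells. For 33 genes simulated at fold 2, the median ratio found was 2.10 and 2.03. A list of 15 genes at fold 2 had a median log2 ratio of 0.99 in both, and an unchanged list stood at percentiles 39.89 and 19.83. The draws follow the same counting model as the intervals, so coverage near the set level was fixed in advance. They hold no spread between cells, no shared variation of list members and no difference between mice. The simulation therefore checks the computation only, not how well intervals and percentiles hold for these data.

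Alternatives were edgeR 4.0.16 TMM scaling, a total without mitochondrial, ribosomal protein, haemoglobin and immunoglobulin genes, cells thinned to 2000 UMIs, a mean over cells, doublets kept, a mitochondrial limit of 10%, a minimum of 1000 UMIs, no filter, libraries merged without integration, other cluster resolutions (0.4 and 1.6), a pseudocount of 10 CPM, and gene minimums of 1 and 100 UMIs. Weighting the clusters of a class alike was added after the data were seen. In alternatives the percentile came from 2000 random lists. Gene ontology enrichment and the rank-sum tests over cells that the design text describes were left out, since cells of 1 mouse are not replicates.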

Results

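Gene expression was measured in single cells of mouse lung by droplet RNA sequencing of 3' ends. Both mice were female C57BL/6JGpt animals of 22 to 24 weeks with a model of pulmonary arterial hypertension in systemic lupus erythematosus, an autoimmune disease. The wild-type group and the Traf5 knockout group each held 1 library. There were no replicates, so no test was possible, and every value below describes these 2 libraries. The wild-type library held 9594 cell barcodes and 68512932 UMIs (counted RNA molecules), and the knockout library held 13019 barcodes and 110738076 UMIs. After filters and removal of called doublets (4.63% and 4.52% of the barcodes that passed the filters), 9006 wild-type and 12245 knockout cells remained. Their median depths were 4812 and 5252 UMIs, over medians of 1747 and 2004 genes. Ratios are knockout over wild type, from CPM, the UMIs summed over the cells of a class scaled to a common total. Intervals in parentheses are exact 95% intervals (Poisson for CPM, binomial for shares and ratios). They cover counting error only, not the difference between any pair of mice. For CPM and gene ratios they treat each UMI as a separate draw, so the spread between cells of a library is not covered either. They are too narrow where few cells hold the UMIs of a gene.

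The comparison asks how the lung of this model differs without TRAF5, an adaptor protein that carries signals from receptors of the tumour necrosis factor family and, in T cells, restrains signalling through the interleukin 6 receptor chain gp130. Traf5 itself (ENSMUSG00000026637; mm10, chromosome 1, 191997205 to 192092559, minus strand) was lower in the knockout library but was still detected. It had 2500 UMIs in the wild-type library, or 39.9 CPM (38.4 to 41.5), and 2013 UMIs in the knockout library, or 19.9 CPM (19.0 to 20.8), a ratio of 0.498 (0.469 to 0.528). B cell-like cells had the highest wild-type level among the classes compared, 107 against 40.6 CPM, a ratio of 0.381 (0.321 to 0.451). The ratio was 0.442 (0.353 to 0.553) in T cell-like cells, 0.438 (0.373 to 0.513) in endothelium-like cells and 0.646 (0.571 to 0.731) in alveolar macrophage-like cells. In interstitial macrophage-like cells (0.698, 0.477 to 1.04) and nonclassical monocyte-like cells (0.759, 0.385 to 1.51) the interval held 1. Ciliated cell-like cells had 63.7 CPM (50.3 to 79.6) in the wild-type and 61.2 CPM (48.0 to 76.8) in the knockout library, from 59 and 66 cells.

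Traf5 UMIs were found in 20.3% (19.4 to 21.1) of wild-type and 13.5% (12.9 to 14.1) of knockout cells. With each cell thinned to 2000 UMIs, which left out 1151 wild-type and 1317 knockout cells, these shares were 7.42% and 3.72%. Neutrophil-like cells, which had the lowest Traf5 level among the classes compared, held Traf5 UMIs in 3.73% and 1.32% of cells at median depths of 4380.5 and 4122 UMIs. The deleted part of the gene is not stated in the labels, and a 3' tag outside the deleted part can persist, so these counts check neither the deletion nor the protein. Among 34 neighbouring genes within 2 Mb that had at least 100 UMIs, the median ratio was 0.929, from 0.419 for Kcnh1, a potassium channel gene, to 1.55 for Nek2, a mitotic kinase gene. These ratios come from UMIs summed over all kept cells, so they also depend on the share of each class. As a check of the sex labels, Xist stood at 651 and 647 CPM, and the Y-linked genes Eif2s3y and Kdm5d had 0 UMIs in both libraries, which allows up to 0.0479 and 0.0296 CPM. Of the other Y-linked genes, Uty had 0 and 1 UMIs and Ddx3y 96 and 222 UMIs, or 1.53 and 2.19 CPM.

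**Figure D1:**
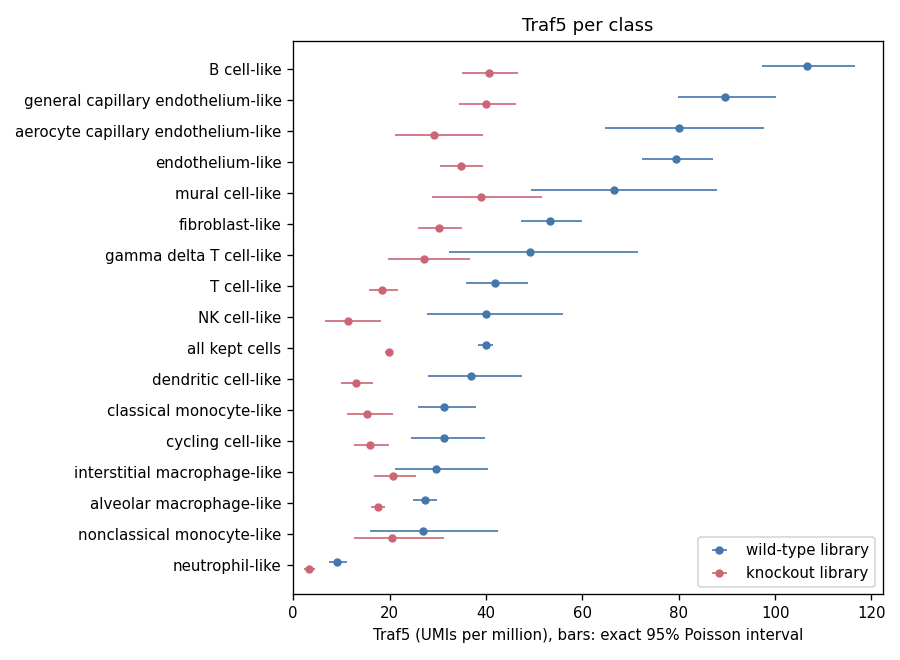
Traf5 in CPM for each class of cells, with the wild-type library in blue and the knockout library in red; bars are exact 95% Poisson intervals. The knockout value lies below the wild-type value in each class drawn, for example 40.6 against 107 in B cell-like cells.

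The make-up of the cells differed in lymphocytes, myeloid cells and stroma. T cell-like cells made up 7.54% (7.0 to 8.10) of wild-type and 11.6% (11 to 12.1) of knockout cells, a ratio of 1.53 (1.40 to 1.68). Gamma delta T cell-like cells were at 1.19% and 2.53% (ratio 2.13, 1.71 to 2.68), and dendritic cell-like cells at 1.32% and 2.53% (1.92, 1.55 to 2.39). B cell-like cells were lower, at 12.1% and 8.68% (0.719, 0.660 to 0.783), as were neutrophil-like cells, at 26.8% and 20.4% (0.761, 0.719 to 0.805). Alveolar macrophage-like cells were at 13.1% and 16.6% (1.27, 1.18 to 1.37) and interstitial macrophage-like cells at 1.93% and 2.83% (1.47, 1.22 to 1.77). Classical monocyte-like cells were lower (4.15% and 2.83%, ratio 0.682) and nonclassical monocyte-like cells higher (1.53% and 2.18%, ratio 1.42). Among named immune cells without neutrophils, the ratio was 1.09 (1.02 to 1.17) for alveolar and 1.26 (1.05 to 1.52) for interstitial macrophage-like cells. There it was 1.32 (1.20 to 1.45) for T cell-like cells and 1.22 (0.991 to 1.51) for nonclassical monocyte-like cells, where the interval held 1.

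Fibroblast-like cells were at 7.65% of wild-type and 4.87% of knockout cells (0.636, 0.569 to 0.711), and endothelium-like cells at 12.7% and 9.91% (0.781, 0.720 to 0.848). Within the named non-immune cells the endothelial share was 52.4% and 51.2% (0.978, 0.901 to 1.06), and the fibroblast share was 31.6% and 25.2% (0.796, 0.712 to 0.890). Mural cell-like cells, which hold smooth muscle cells and pericytes, were at 1.04% and 1.07% (1.02, 0.780 to 1.35). Club or secretory cell-like cells were at 0.50% and 0.980% (1.96, 1.38 to 2.83). All immune classes together made up 72.0% and 73.0%. Unnamed clusters held 2.64% and 5.74% of cells, most of the gap in cluster 12, a low-depth cluster (medians of 976.5 and 1102 UMIs) led by Scgb3a1 and Fabp5 with 0.622% and 3.29%. Each share comes from 1 dissociated lung per group. The ratio of unnamed cells, 2.17 (1.87 to 2.53), was 5.77 with a minimum of 1000 UMIs, 4.72 with a mitochondrial limit of 10% and 1.31 with libraries merged without integration. With libraries merged, the unnamed cells took in a cluster of 215 wild-type and 81 knockout cells. Its leading genes included Nlrp12 and Csf3r, which also lead the neutrophil-like cluster 4 of the main run. The cluster led by Scgb3a1 and Fabp5 stayed at 0.611% and 3.22% there.

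**Figure D2:**
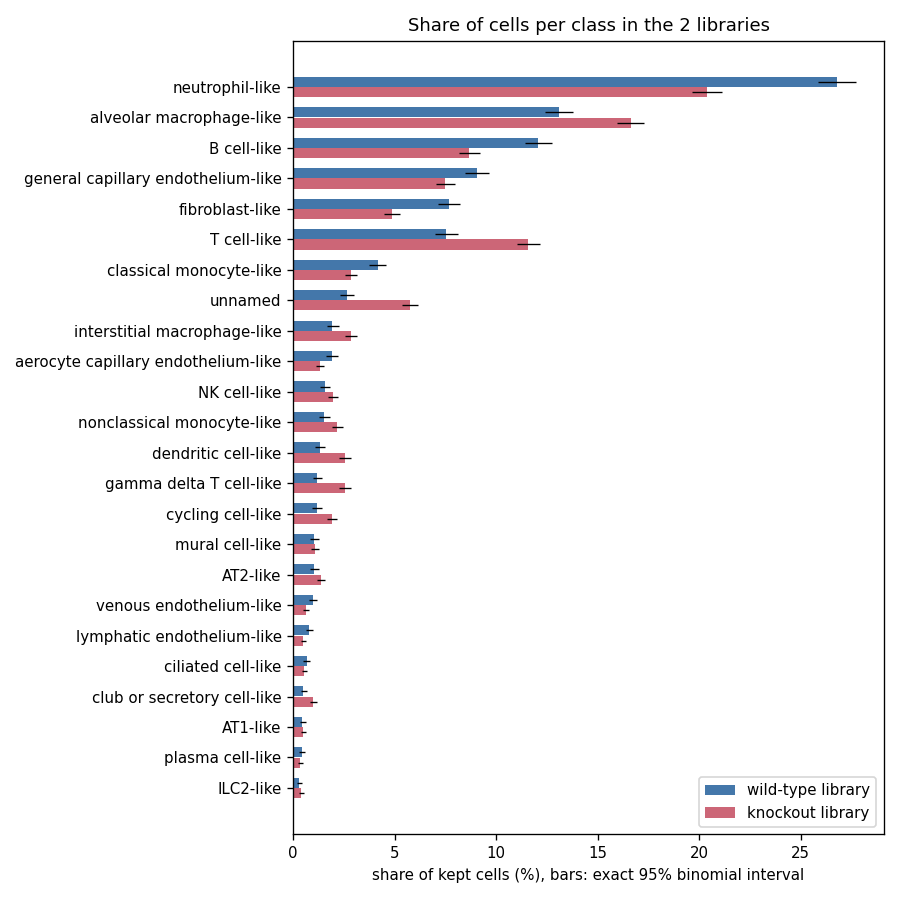
Share of kept cells in percent for each class, with the wild-type library in blue and the knockout library in red; bars are exact 95% binomial intervals. T cell-like cells are at 7.54% and 11.6%, and neutrophil-like cells at 26.8% and 20.4%.

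Gene groups were lists fixed before the data were examined. A list's value is the median over its measured members of the log2 ratio with a pseudocount of 1 CPM. Its percentile among 10000 random lists of the same size and expression is given as a description of these libraries. The middle range is the central 95% of random lists, and members are counted as higher or lower beyond 1.5-fold. Members of a list vary together, so a percentile is no measure of chance between mice.

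T cell-like cells of the knockout library had higher medians of the activation, regulatory, cytotoxic, cytokine and Th17 lists and lower medians of the naive T cell and type I interferon lists. The activation and exhaustion list stood at 0.91 (percentile 100; 12 members measured, 8 more than 1.5-fold higher and 0 lower). Pdcd1, which encodes the inhibitory receptor PD-1, was at 30.4 and 79.8 CPM, a ratio of 2.63 (2.17 to 3.21). Lag3 (6.05, 2.65 to 17), Havcr2 (4.64, 2.72 to 8.52) and Tnfrsf9, the gene of the costimulatory receptor 4-1BB (2.61, 2.21 to 3.10), were also higher. The regulatory T list stood at 0.54 (percentile 100; 5 of 10 members more than 1.5-fold higher), with Il2ra at a ratio of 2.12, Icos at 1.69 and Il10, an anti-inflammatory cytokine gene, at 6.78 (3.32 to 16.1). The naive T cell list stood at -0.35 (percentile 0; 2 of 10 members more than 1.5-fold lower), with Ccr7 at 0.701, Klf2 at 0.736 and Igfbp4 at 0.530.

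The cytotoxic list stood at 0.53 in T cell-like cells (percentile 100; 6 of 12 members more than 1.5-fold higher). Its members included the granzyme genes Gzma (6.41, 3.85 to 11.4) and Gzmb (3.80, 2.29 to 6.73), the cytokine gene Ifng (14.0 and 38.8 CPM; 2.78, 2.10 to 3.76) and Tbx21, which encodes T-bet (2.25, 1.74 to 2.94). Gzma was among the fixed NK cell markers, and Gzma, Gzmb and Ccl5 are leading genes of the NK cell-like cluster. Whether NK cells or their RNA inside the T cell-like class add to this list was not tested. The cytokine and chemokine list stood at 0.36 (percentile 99.92; 11 of 23 members higher and 1 lower), with Ccl3 at 2.99 and Spp1 at 4.43. The Th17 list stood at 0.40 (percentile 99.99; 5 of 14 members higher), with Rora at 2.06 (1.93 to 2.20), Il1r1 at 3.16, Maf at 1.77 and Ahr at 1.63. Inside clusters 5 and 6 of the class, taken up below, the Th17 list was at -0.04 (percentile 24.19) and 0.38 (percentile 98.25). The list of receptors that TRAF5 binds and related receptors stood at 0.28 (percentile 98.02; 4 of 11 members higher), with Tnfrsf4 at 1.83, Tnfrsf1b at 1.57 and Cd27 at 0.714. It is shortened below to TRAF5 receptors, although not every member is a receptor that TRAF5 binds. Inside clusters 5 and 6 this receptor list was at 0.02 (percentile 50.55) and -0.02 (percentile 26.28), both inside the middle range. The NF-kB target list stood at 0.12 (percentile 78.56; 3 of 21 members higher and 1 lower), with Nfkbiz at 1.56 and Icam1 at 1.52. The median of the type I interferon response list was lower, at -0.31 (percentile 0; 27 of 36 members within 1.5-fold, 9 lower and 0 higher), with Isg15 at 75.1 and 29.7 CPM (0.395, 0.333 to 0.469), Ifit3 at 0.448 and Rtp4 at 0.582. Outside the lists, Tnfsf11, the gene of RANKL, was at 2.61 (2.22 to 3.09), Cdk5rap1 at 3.91 and Chst2 at 3.25. Slc15a2, a peptide transporter gene, was at 0.414 (0.365 to 0.471). Dapl1, a member of the naive T cell list, was at 0.364 (0.331 to 0.401).

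Cluster 6, led by Dapl1, Lef1 and Cd8b1, held 57.6% of wild-type T cell-like cells, whereas cluster 5, led by Ctla4, Tnfrsf4, Icos and Tnfsf11, held 61.0% of knockout ones. Inside cluster 5 the activation list stood at 0.50 (percentile 100), the regulatory list at 0.31 and the cytotoxic list at 0.10 (percentile 79.64). Inside cluster 6 they stood at 0.06 (percentile 56.79), -0.00 and 0.78 (percentile 100). The naive list was at -0.42 in cluster 5 and 0.02 in cluster 6, and the interferon list at -0.39 and -0.18. Median depth was 5784 and 5375 UMIs, and the lists of free RNA from other cell types and of ribosomal proteins stood at -0.04 and -0.16 (percentile 0). With the clusters weighted alike the Th17 list was at -0.05 and the TRAF5 receptor list at -0.02, and the receptor list was at -0.00 with a minimum of 1 UMI per gene and inside the middle range in 5 more settings. The regulatory list (0.20 as a mean over cells), the cytotoxic list (0.16 with a mitochondrial limit of 10%) and the cytokine list (0.10 with that limit, 0.25 with a minimum of 100 UMIs per gene) were also inside the middle range in those settings.

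Gamma delta T cell-like cells, whose cluster is led by Cd163l1, Il23r and Il17a, had a Th17 list at -0.03 (percentile 38.12; 0 of 13 members more than 1.5-fold higher and 1 lower). Rorc, which encodes the Th17 master regulator, was at 215 and 105 CPM, a ratio of 0.490 (0.385 to 0.627), and Ahr was at 1.40. In NK cell-like cells the cytotoxic list stood at -0.14 (percentile 2.90), with all 12 members within 1.5-fold, among them Gzmb at 0.850, Nkg7 at 0.799 and Klrg1 at 0.707. The free RNA list stood at 0.18 in gamma delta T cell-like and 0.62 in NK cell-like cells, where the mitochondrially encoded list stood at -0.17 (percentile 0.87), and median depths were 4851 and 4776 UMIs (107 and 310 cells) and 5590 and 5707 UMIs (139 and 237 cells). The NK cell list, just inside the middle range here, was below it in 7 settings, not counting those that scale all genes of a class alike.

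B cell-like cells of the knockout library had a higher age-associated B cell list. Medians of the MHC class II, oxidative phosphorylation, type I interferon, ribosomal protein and dissociation lists were below the middle range by small amounts, with most members within 1.5-fold. The age-associated list stood at 0.62 (percentile 99.96; 4 of 7 members more than 1.5-fold higher and 0 lower). Fcrl5, an Fc receptor-like gene, was at 27.2 and 61.9 CPM (2.27, 1.84 to 2.83), Zbtb32 at 2.99 (1.85 to 5.0) and Ahnak at 2.34 (2.02 to 2.72). The MHC class II list stood at -0.25 (percentile 0.02), with each of its 10 members within 1.5-fold, such as Cd74, the invariant chain gene (10495 and 8431 CPM, 0.803), and H2-DMa (0.762). The oxidative phosphorylation list stood at -0.20 (percentile 0; 20 of 20 members within 1.5-fold), with Ndufs7 at 0.706 and Sdhb at 0.784. Type I interferon response genes stood at -0.19 (percentile 0.02; 5 of 36 members lower), with Isg15 at 0.417 (0.294 to 0.585), Rsad2 at 0.521 and Rtp4 at 0.596. The ribosomal protein list was at -0.11 (percentile 0; 1 of 88 members higher and 0 lower) and the dissociation and heat shock list at -0.13 (percentile 0.27; 1 of 22 members higher and 1 lower), with Hsp90ab1 at 1.70 and Zfp36 at 0.680 and a summed ratio of 1.05 (1.03 to 1.07).

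Lists nearer to TRAF5 signalling in B cell-like cells were inside the middle range of random lists. The receptor list stood at 0.06 (percentile 52.43), with Cd40 at 0.871 (0.736 to 1.03) and Tnfrsf13b at 0.764. The NF-kB list stood at 0.16 (percentile 90.17), with 21 of 21 members within 1.5-fold, Nfkb1 at 1.31 and Rel at 1.26. The germinal centre list stood at 0.03 (percentile 48.48; 4 of 8 members measured), with Bcl6 at 1.10. Among single genes, Sox5 was at 102 and 255 CPM (2.49, 2.24 to 2.78), Ptpn22, a phosphatase gene tied to lupus risk, at 2.09 (1.90 to 2.30), Il9r at 2.27 and Stip1 at 2.33. Slc15a2 was at 0.362 (0.317 to 0.413) and Sertad3 at 0.360. Median depth was 3843 and 4025 UMIs, and the free RNA list stood at 0.07 (ratio of summed UMIs 0.910). The NF-kB list was at 0.20 as a mean over cells and then above the middle range.

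Alveolar macrophage-like cells of the knockout library had higher medians of the type I interferon, interferon gamma, MHC class I, alternative activation, lipid handling and cytokine lists and a lower median of the dissociation and heat shock list, with most members of each within 1.5-fold. Type I interferon response genes stood at 0.27 (percentile 100; 6 of 36 members higher and 1 lower), with Rsad2 at 2.72 (1.81 to 4.22), Oas2 at 2.21 and Oas3 at 2.66. The interferon gamma list stood at 0.22 (percentile 99.98; 4 of 16 members higher), with the chemokine gene Cxcl9 at 7.16 and 25.4 CPM (3.55, 2.93 to 4.33) and Iigp1 at 4.64. The MHC class I list stood at 0.31 (percentile 100; 3 of 15 members higher), with H2-K1 at 1.44 (1.40 to 1.47) and Nlrc5, which encodes an activator of MHC class I genes, at 2.43. The alternative activation list stood at 0.40 (percentile 100; 4 of 11 members higher and 1 lower). In it Arg1 was at 8.84 (3.65 to 27.9) and Trem2 at 64.7 and 138 CPM (2.13), while Retnla was at 0.234 (0.158 to 0.342). The lipid handling list stood at 0.19 (percentile 99.92; 2 of 14 members higher), with Fabp5 at 1.54, Lipa at 1.52 and Ctsd at 1.33. The cytokine list stood at 0.11 (percentile 99.87; 9 of 31 members higher and 4 lower), with Ccl17 at 3.39, Ccl5 at 2.95 and Cxcl3 at 0.409.

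The dissociation and heat shock list stood at -0.25 in alveolar macrophage-like cells (percentile 0.01; 5 of 22 members more than 1.5-fold lower), with the immediate early genes Egr1 at 639 and 274 CPM (0.429, 0.417 to 0.441), Jun at 0.496 and Ier2 at 0.513. Single genes with high ratios were Syngr1 (10.7, 8.01 to 14.7), Akr1b8 (5.20, 3.87 to 7.12) and Zranb3 (3.07), and Ereg, a growth factor gene, was at 0.423. Syngr1, Gpnmb, Ctsk and Fabp5 are leading genes of cluster 7, which held 19.1% of wild-type and 31.2% of knockout cells of this class, and cluster 1 held most of the class in both libraries. In clusters 1 and 7 the type I interferon list was at 0.15 and 0.32, the MHC class I list at 0.20 and 0.34, and the alternative activation list at 0.37 and 0.39. Median depth was 14770.5 and 16251 UMIs, and the free RNA and ribosomal protein lists stood at -0.22 and 0.12 (percentile 100). The interferon gamma list was at 0.11 after thinning, inside the middle range, and the cytokine list was at -0.05 with clusters weighted alike.

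Interstitial macrophage-like cells of the knockout library differed in many lists. Medians of the hypoxia, lipid handling and cytokine lists were above the middle range, and those of the type I interferon, complement and alternative activation lists below it. Cxcl9 was at 2.97 and 166 CPM (4 and 736 UMIs; ratio 55.9, 21.7 to 206) and Ccl5 at 12.4 (7.82 to 21.1). The cytokine and chemokine list stood at 0.34 (percentile 100; 13 of 32 members higher and 9 lower). The hypoxia list stood at 0.72 (percentile 100; 11 of 19 members higher and 0 lower), with Vegfa, an angiogenic factor gene, at 5.13 (3.15 to 8.92), the glucose transporter gene Slc2a1 at 2.12 and the glycolysis genes Pgk1 and Pgam1 at 2.10 and 2.13. The lipid handling list stood at 0.60 (percentile 100; 7 of 14 members higher and 1 lower), with Ctsk at 3.09, Lgals3 at 2.73 and Abcg1 at 2.18. Its summed UMIs were lower in the knockout library, at a ratio of 0.841 (0.830 to 0.852), with the abundant member Apoe at 0.514 (0.505 to 0.523). The type I interferon list stood at -0.63 (percentile 0; 21 of 36 members more than 1.5-fold lower and 1 higher), with Isg15 at 0.565, Oasl2 at 0.526 and Parp14 at 0.528.

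The complement list stood at -0.65 in interstitial macrophage-like cells (percentile 0.03; 7 of 12 members lower and 2 higher), with Cfh at 659 and 238 CPM (0.360), C4b at 0.395, C3 at 2.28 and Cfb at 3.0. The alternative activation list stood at -0.81 (percentile 0; 7 of 14 members lower and 3 higher). Its member Lyve1 was at 0.320 (0.272 to 0.375) and Ccl24 at 0.212 (0.167 to 0.269), whereas Arg1 was at 14.6 (6.61 to 40.0) and Fn1 at 135 and 958 CPM (7.09, 6.11 to 8.27). The dissociation list stood at -0.43 (percentile 0.02; 8 of 22 members lower and 1 higher), with Jun at 0.484 and Hspe1 at 1.74. These cells had the widest depth gap of the classes compared gene by gene, 6502.5 and 11131 UMIs, over 174 and 347 cells, and the free RNA and ribosomal protein lists stood at -0.55 and 0.17 (percentile 99.64). TMM scaling shifted all genes of this class by 0.12 log2. After thinning, the lipid list was at 1.22 and the alternative activation list at -0.29, and as a mean over cells the dissociation list was at -0.03, the latter pair inside the middle range.

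Dendritic cell-like cells had lower type I interferon and dissociation lists and higher complement and cytokine lists. The type I interferon list stood at -0.37 (percentile 0; 12 of 35 members lower and 2 higher), with Rsad2 at 0.399 (0.288 to 0.554), Usp18 at 0.558 and Oasl1 at 3.22. The cytokine and chemokine list stood at 0.17 (percentile 99.57; 9 of 26 members higher and 4 lower), with Ccl3 at 5.57 (3.66 to 8.89), Cxcl9 at 4.81 (2.99 to 8.25) and Ccl4 at 2.17. The dissociation and heat shock list stood at -0.34 (percentile 0; 4 of 22 members lower and 1 higher), with Ier3 at 0.603 and Zfp36 at 0.641. The complement list stood at 1.18 (percentile 100; 5 of 9 members higher), with C1qa at 7 and 148 UMIs (6.96, 3.30 to 17.6) and C1qb at 15 and 259 UMIs (5.69, 3.38 to 10.3), both markers of interstitial macrophages. The cell cycle list, at 0.12 (percentile 95.20; 8 of 19 members higher), was inside the middle range, with Top2a at 2.01. Median depth was 12406 and 13919 UMIs over 119 and 310 cells, and the free RNA list stood at 0.17 (ratio of summed UMIs 0.846). After thinning the interferon list was at -0.12 and the complement list, with 4 members, at 0.17, and with libraries merged without integration the cytokine list was at 0.08, each inside the middle range. The cell cycle list was above it in 3 settings (0.28 as a mean over cells).

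Classical monocyte-like cells of the knockout library had higher NF-kB, cytokine, MHC class II and complement lists and a lower cell cycle list. The NF-kB list stood at 0.57 (percentile 100; 11 of 22 members higher and 0 lower), with the neutrophil-attracting chemokine gene Cxcl2 at 170 and 568 CPM (3.35, 3.05 to 3.69), Relb at 1.82, Nfkbie at 1.80 and Ier3 at 1.88. The cytokine list stood at 0.51 (percentile 100; 9 of 19 members higher and 0 lower), with Il1a at 3.38 (2.02 to 5.86), Spp1 at 7.19 (4.98 to 10.7) and Ccl4 at 1.94. The MHC class II list stood at 1.24 (percentile 100; 4 of 7 members higher), with H2-Ab1 at 3.37 (2.62 to 4.36) and Cd74 at 169 and 401 CPM (2.37), levels far below those of B cell-like cells. The cell cycle list stood at -1.003 (percentile 0; 11 of 14 members lower), with Mcm6 at 56 and 13 UMIs (0.284, 0.142 to 0.525), and was at -0.41 after thinning, with 4 members and inside the middle range. The complement list stood at 0.58 (percentile 99.98; 5 of 10 members higher), but its abundant members C3 (0.935) and Cfp (0.937) were near 1, and it was at -0.05 after thinning and 0.02 with a minimum of 100 UMIs per gene. The type I interferon list stood at 0.09 (percentile 97.01), with 36 of 36 members within 1.5-fold, among them Irf7 at 1.45. Nrg1 was at 296 and 614 CPM (2.07, 1.92 to 2.24) and Fkbp5, a glucocorticoid-responsive gene, at 2.17 (1.80 to 2.62), while Jun was at 0.504 and Chil3 at 0.651. In nonclassical monocyte-like cells the interferon gamma list stood at -0.95 (percentile 0.01), but only 8 of its 20 members were measured, and Irf1 (1.11, 0.836 to 1.48) and Cd274 (0.861, 0.706 to 1.05) were near 1. With a minimum of 1 UMI that list was at -0.21, inside the middle range. Median depths were 9193 and 8098 UMIs in classical and 4349 and 3477 in nonclassical monocyte-like cells, the free RNA list stood at -0.29 and -0.09, and the ribosomal protein list at -0.05 (percentile 2.45) and 0.06 (percentile 98.60).

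Neutrophil-like cells had a higher NF-kB list, while the list of granule and maturation genes was inside the middle range, at 0.07 (percentile 85.96; 3 of 17 members higher and 1 lower). Of the granule genes, Camp (66.5 and 252 CPM; 3.78, 3.48 to 4.12) was seen in 0.954% and 1.603% of cells, Ltf (2.86, 2.55 to 3.21) in 1.66% and 1.28%, and Ngp (2.52, 2.38 to 2.67) in 8.21% and 8.94%. Their UMIs come from few cells, so these intervals are too narrow for the spread between cells. The NF-kB list stood at 0.18 (percentile 99.92; 2 of 23 members higher), with Cd83 at 1.97, Ccl2 at 2.09 and Nfkb1 at 1.44. Interferon-stimulated genes of the type I list stood at 0.06 (percentile 93.95), with all 33 members within 1.5-fold, such as Ifit3 and Rsad2, both at 1.36, and at 0.06 it was above the middle range with clusters weighted alike. Cdk5rap1 was at 1.12 and 15.8 CPM (14.1, 7.86 to 27.8), Fkbp5 at 2.14 and Prok2 at 2.06. Slc15a2 was at 0.492 and Ddit3, a stress response gene, at 0.513 (0.483 to 0.544). Cluster 4 held 28.5% of wild-type and 40.2% of knockout neutrophil-like cells, and cluster 0 the others. Inside cluster 4 the NF-kB list was at 0.64 (percentile 100) and inside cluster 0 at 0.10 (percentile 96.77). Median depth was 4380.5 and 4122 UMIs. The free RNA list stood at 0.57, while its summed UMIs had a ratio of 0.853 (0.842 to 0.864), and the ribosomal protein list stood at 0.17 (percentile 100).

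Endothelium-like cells of the knockout library had higher medians of the interferon, MHC, NF-kB, cytokine, IL-6 and STAT3, hypoxia and dissociation lists and a slightly lower median of the vasoactive list, with most members of each within 1.5-fold except in the cytokine list. The interferon gamma list stood at 0.48 (percentile 100; 9 of 20 members higher and 0 lower), with Cxcl10 at 2.47 and 31.3 CPM (12.7, 7.41 to 23.6), Cxcl9 at 5.07 (3.25 to 8.26), Nos2 at 2.27 and Ido1 at 2.01. The MHC class I list stood at 0.31 (percentile 100), with 15 of 15 members within 1.5-fold, among them Nlrc5 at 1.43 and H2-Q7 at 1.34. The capillary classes differed in size of both lists. In aerocyte cells the interferon gamma list was at 0.97 (14 of 19 members higher) and MHC class I at 0.39 (6 of 15). In general capillary cells they were at 0.35 (6 of 20) and 0.21 (0 of 15). The MHC class II list stood at 0.39 (percentile 100; 1 of 9 members higher and 1 lower), with Cd74 at 1574 and 2376 CPM (1.51). Genes of the type I interferon response stood at 0.15 (percentile 100; 3 of 35 members higher), with Zbp1 at 1.73 and Rsad2 at 1.58. The NF-kB list stood at 0.24 (percentile 100; 4 of 23 members higher and 1 lower), with Cd83 at 3.26 and Ptgs2, which encodes cyclooxygenase 2, at 1.74. The cytokine list stood at 0.43 (percentile 100; 11 of 25 members higher and 4 lower), with Ccl4 at 4.08 and Spp1 at 0.304, the IL-6 and STAT3 list at 0.26 (percentile 99.98), with Osmr at 1.44, and the hypoxia list at 0.13 (percentile 99.91; 5 of 23 members higher and 2 lower), with Pfkfb3 at 2.01 and Adm at 0.307. The dissociation and heat shock list stood at 0.16 (percentile 99.88; 4 of 22 members higher), with Hspa1b at 1.91. With called doublets kept, the cytokine and NF-kB lists were no longer above the middle range.

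For the vessel wall, the vasoactive list stood at -0.17 in endothelium-like cells (percentile 0.27; 4 of 19 members lower and 0 higher), and the free RNA list was lower too. Gucy1a3 (0.252, 0.147 to 0.416) and Gucy1b3 (0.497, 0.358 to 0.685), which encode subunits of the nitric oxide receptor guanylate cyclase, were lower, as were the vasodilator peptide gene Adm (0.307, 0.209 to 0.443) and Npr3 (0.595). Gucy1a3 is a leading gene of the mural cluster, at 698 and 611 CPM there against 11.99 and 3.02 CPM in endothelium-like cells, and was at 0.915 in general capillary endothelium-like cells. The BMP signalling list stood at -0.09 (percentile 6.72; 1 of 14 members more than 1.5-fold lower), with Bmp4 at 0.596 (0.489 to 0.725), Smad6 at 0.818 and Bmp6 at 0.819. The list of pulmonary hypertension genes stood at -0.09 (percentile 9.37), with 14 of 14 members within 1.5-fold, such as Kdr at 0.841 and Klf2 at 1.20. The adhesion list stood at 0.09 (percentile 82.0; 2 of 9 members higher), with Vcam1 at 1.79 (1.53 to 2.10) and Selp at 1.68 (1.40 to 2.03). The list for endothelial to mesenchymal transition stood at -0.36 (percentile 0.03; 3 of 13 members lower), with S100a4 at 0.498, Zeb2 at 0.723 and Col3a1 at 0.600.

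Among single genes of endothelium-like cells, Zbtb16, a transcription factor gene induced by glucocorticoids, was at 61.3 and 582 CPM (9.48, 8.50 to 10.6). Cyp26b1, which encodes an enzyme that degrades retinoic acid, was at 4.70 (4.17 to 5.32), Tmem252 at 3.80, Pknox2 at 3.54 and Fkbp5 at 3.26 (2.59 to 4.14). Nr1d1, a repressor of the circadian clock, was at 30.3 and 4.17 CPM (0.138, 0.0894 to 0.205), Hs3st1 at 0.424 and Sox11 at 0.445. In general capillary endothelium-like cells alone, Zbtb16 was at 9.44, Cyp26b1 at 4.67, Sema5a at 4.19 and Hs3st1 at 0.362. Median depth was 3518.5 and 4036 UMIs, and the free RNA list stood at -0.46, the ribosomal protein list at 0.14 (percentile 100) and the mitochondrially encoded list at -0.13 (percentile 0.89). With called doublets kept, the cytokine list was at -0.07 and the NF-kB list at 0.05; the mesenchymal list was inside the middle range in 3 settings, and the BMP list was at -0.14 and outside it after thinning.

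Fibroblast-like cells of the knockout library had higher medians of the interferon, MHC, NF-kB, IL-6 and STAT3, cytokine and dissociation lists. Most measured members were beyond 1.5-fold in the interferon gamma and MHC class II lists, but not in the others. In the same cells the list of free RNA from other cell types stood at 0.74 (percentile 100; ratio of summed UMIs 1.80). Pan leukocyte genes stood at 0.46 (percentile 100). The interferon gamma list stood at 0.60 (percentile 100; 9 of 17 members higher and 0 lower), with Cxcl9 at 3 and 267 UMIs (78.2, 26.5 to 382), Iigp1 at 197 and 440 CPM (2.24) and Cd274, which encodes PD-L1, at 2.38. The MHC class I list stood at 0.55 (percentile 100; 6 of 15 members higher), with H2-K1 at 502 and 839 CPM (1.67) and Nlrc5 at 2.38, and the MHC class II list at 0.82 (percentile 100; 5 of 9 members higher), with H2-Ab1 at 2.31 (2.03 to 2.63) and Cd74 at 1.91. Genes of the type I interferon response stood at 0.32 (percentile 100; 10 of 36 members higher and 0 lower), with Ifi44 at 2.45 and Rsad2 at 1.68. The NF-kB list stood at 0.44 (percentile 100; 5 of 23 members higher), with Traf1 at 4.50 (2.61 to 8.24), Birc3 at 1.62 and Tnfaip3 at 1.56. The IL-6 and STAT3 list stood at 0.32 (percentile 100; 2 of 15 members higher), with Il6 at 139 and 246 CPM (1.77) and Saa3 at 1.75, and the cytokine list at 0.48 (percentile 100; 11 of 28 members higher), with Ccl4 at 9.22 (4.01 to 26.1) and Ccl5 at 2.40. The dissociation and heat shock list stood at 0.28 (percentile 100; 1 of 22 members higher), with Fosb at 1.53. In the 2 clusters of the class, 8 (386 and 374 cells) and 10 (303 and 222 cells), the type I interferon list was at 0.42 (percentile 100) and 0.06 (percentile 92.62) and the dissociation list at 0.36 (percentile 100) and -0.06 (percentile 18.77).

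The synthetic and contractile lists were also higher in fibroblast-like cells, with 4 of 14 members of each beyond 1.5-fold. The synthetic list stood at 0.27 (percentile 99.98; 4 of 14 members higher), with the matricellular genes Tnc (18.5 and 77.4 CPM; 4.17, 3.34 to 5.26) and Thbs1 (2.29, 2.14 to 2.46). The contractile list stood at 0.30 (percentile 99.96; 4 of 14 members higher), with Acta2, the smooth muscle actin gene, at 21.4 and 65.5 CPM (3.06, 2.47 to 3.81) and Myl9 at 1.63. Acta2 and Myl9 are leading genes of the mural cluster, and whether RNA of mural cells adds to these values was not tested. The extracellular matrix list stood at 0.09 (at the upper limit of the middle range; 2 of 23 members higher), with Serpine1 at 1.72 and Postn at 1.47. Zbtb16 was at 96.0 and 571 CPM (5.95, 5.42 to 6.55), Angptl4 at 4.17 (3.60 to 4.84), and the glucocorticoid-responsive genes Fkbp5 and Tsc22d3 at 2.76 and 2.58. Nr1d1 was at 505 and 38 UMIs (0.0661, 0.0462 to 0.0920), Nrg2 at 0.454 and Agtr1b, an angiotensin receptor gene, at 0.380. Median depth was 6161 and 9326.5 UMIs, and the free RNA and mitochondrially encoded lists stood at 0.74 and -0.15 (percentile 1.18). The contractile list was at 0.03 as a mean over cells and inside the middle range, as was the matrix list in 4 settings, not counting TMM scaling.

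Mural cell-like cells mix smooth muscle cells and pericytes and, with 94 wild-type cells, were under the planned minimum of 100. Medians of the synthetic and extracellular matrix lists were higher and that of the contractile list was lower, with most members of the latter pair within 1.5-fold. The synthetic list stood at 0.56 (percentile 100; 7 of 14 members higher and 1 lower), with Mgp at 3023 and 6010 CPM (1.99), Thbs1 at 1.74 and Spp1 at 0.368 (0.325 to 0.417). The extracellular matrix list stood at 0.22 (percentile 99.75; 3 of 22 members higher), with the elastin gene Eln at 1.71 (1.6 to 1.83) and Lox at 1.57. The contractile list stood at -0.24 (percentile 0.02; 1 of 16 members lower and 1 higher), with the smooth muscle myosin gene Myh11 at 0.772 (0.733 to 0.813), Lmod1 at 0.654 and Myocd at 1.61. The dissociation and heat shock list was higher in the same cells, at 0.30 (percentile 100; 4 of 22 members higher and 0 lower), with Hspa1b at 2.60 (2.12 to 3.20). The BMP list (-0.08, percentile 11.92), the vasoactive list (-0.04, percentile 21.82) and the pulmonary hypertension list (-0.05, percentile 24.54) stood inside the middle range, with Id2 at 0.680, Edn1, the endothelin gene, at 1.92 (1.31 to 2.87), Ednrb at 0.480 and Kcnk3 at 0.755. Median depth was 6777.5 and 7865 UMIs. The free RNA list stood at 0.56, while its summed UMIs had a ratio of 0.654 (0.628 to 0.681), and the mitochondrially encoded list stood at -0.17 (percentile 1.13). As a mean over cells the matrix list, at 0.22, was inside the middle range.

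Across the study, 281 pairs of a fixed list and a planned class could be measured, and 99 stood at or above the upper and 44 at or below the lower limit of the middle range; the 85 pairs described here were picked after their values were seen, as were the ribosomal protein and mitochondrially encoded values given beside depth. The direction of the interferon lists differed between classes. The type I list was above the middle range in alveolar macrophage-like (0.27), endothelium-like (0.15; 0.19 in aerocyte and 0.15 in general capillary), fibroblast-like (0.32) and cycling cell-like cells (0.11). In the latter its summed UMIs were lower (0.924, 0.891 to 0.959), and the free RNA list stood at 0.81 (percentile 100; ratio of summed UMIs 3.29). The type I list was below the middle range in T cell-like (-0.31), B cell-like (-0.19), dendritic cell-like (-0.37), interstitial macrophage-like (-0.63) and nonclassical monocyte-like cells (-0.26). The dendritic cell-like, nonclassical monocyte-like and aerocyte values came inside the middle range after thinning (-0.12, -0.22 and 0.11), and the latter pair also with a minimum of 100 UMIs per gene (-0.16 and 0.14). As a mean over cells the aerocyte value was 0.07, and the cycling cell-like value, at -0.08 after thinning, was inside the range in 4 more settings, not counting those that scale all genes alike.

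**Figure D3:**
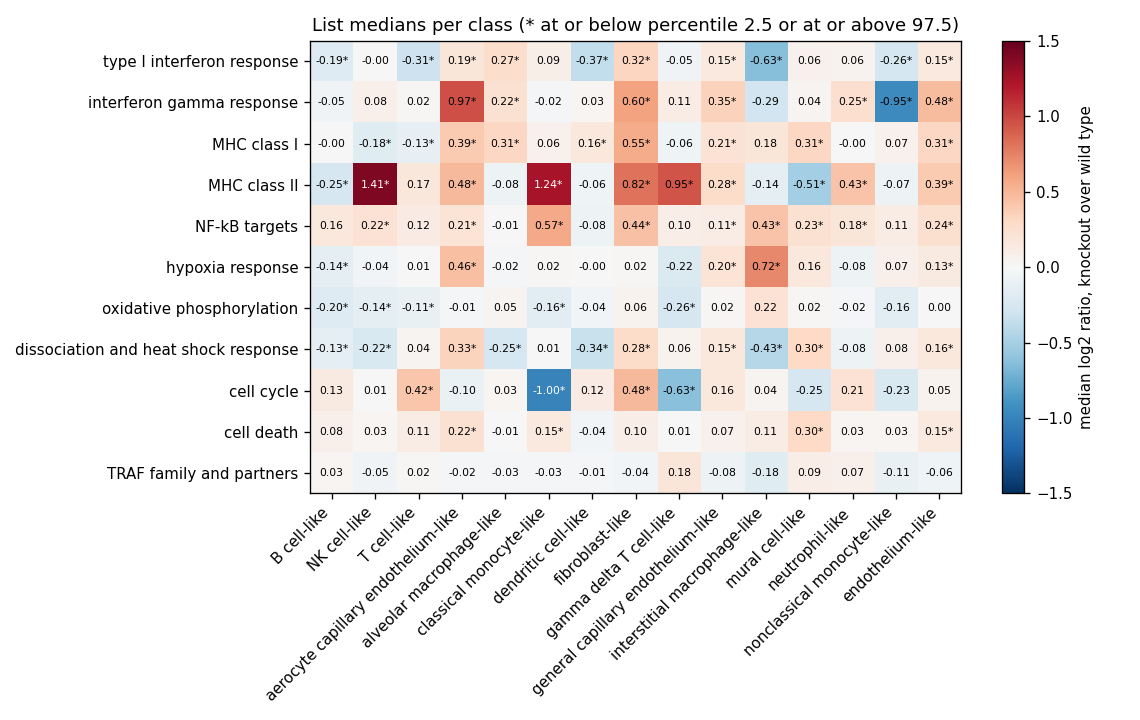
Median log2 ratio, knockout over wild type, of 11 fixed gene lists in 15 classes; a star marks a median at or outside the limits of the central 95% of matched random lists. The type I interferon list runs from -0.63 in interstitial macrophage-like cells to 0.32 in fibroblast-like cells.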

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

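No paired analysis was possible because each group has 1 library. Weighting the clusters of a class alike was chosen after seeing the data; the other alternatives were planned. Traf5 kept its ratio within its interval in both alternatives. Of the shares under alternatives, 157 stayed inside the interval of the main value and 9 moved. Of the list medians, 829 were counted as unchanged, 40 were weaker (came inside the middle range), 15 stronger (left it) and 7 reversed. Unchanged lists that lay outside the middle range in the main run stayed outside on the same side. Lists inside it were not checked for a change of sign or a move past the opposite limit. Of the ratios of genes that the rule took per class and direction, 645 stayed inside their interval and 87 moved, with no change of direction. These genes had been picked from the same data for a large ratio and an interval far from 1. A change of direction was therefore unlikely from the start, and its absence says little. Genes named only as list members were not run under the alternatives. Unless said otherwise the values below are list medians (log2), and the cause was not tested.

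With clusters weighted alike, 3 lists turned: Th17 in T cells (-0.0532), TRAF5 receptors in T cells (-0.0219) and cytokines in alveolar macrophages (-0.0462). There the mesenchymal transition list in endothelium (-0.16) was weaker and type I interferon in neutrophils (0.0578) stronger. With doublet calls kept, cytokines in endothelium turned (-0.0695), NF-kB targets in endothelium (0.052), extracellular matrix in fibroblasts (0.0572), TRAF5 receptors in T cells (0.17) and type I interferon in cycling cells (0.0798) were weaker, the cytotoxic list in NK cells (-0.18) was stronger, and the share ratio of unnamed cells was 2.61. With at least 1 UMI per gene, TRAF5 receptors in T cells turned (-0.0043) and interferon gamma response in nonclassical monocytes (-0.21) was weaker. With at least 100 UMIs, TRAF5 receptors (0.23) and cytokines (0.25) in T cells and the mesenchymal list in endothelium (-0.14) were weaker, complement in classical monocytes was at 0.0164, type I interferon was weaker in nonclassical monocytes (-0.16), aerocytes (0.136) and cycling cells (0.11), and the NK cytotoxic list (-0.15) was stronger.

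After thinning to 2000 UMIs, weaker lists were TRAF5 receptors in T cells (0.0931), interferon gamma response in alveolar macrophages (0.11), alternative activation in interstitial macrophages (-0.29), type I interferon (-0.12) and complement (0.17) in dendritic cells, type I interferon in nonclassical monocytes (-0.218) and aerocytes (0.1079), cell cycle in classical monocytes (-0.41), the mesenchymal list in endothelium (-0.22) and extracellular matrix in fibroblasts (0.13); complement in classical monocytes (-0.0452) and type I interferon in cycling cells (-0.0833) turned, and the NK cytotoxic list (-0.28) and BMP signalling in endothelium (-0.14) were stronger. As a mean over cells, weaker lists were regulatory T (0.20) and TRAF5 receptors (0.10) in T cells, dissociation in interstitial macrophages (-0.029), matrix (0.0365) and contractile genes (0.0268) in fibroblasts, type I interferon in aerocytes (0.074) and cycling cells (0.0865) and matrix in mural cells (0.22), and stronger ones the NK cytotoxic list (-0.18), NF-kB targets in B cells (0.20) and cell cycle in dendritic cells (0.28, also 0.20 with doublet calls kept and 0.16 with libraries merged). With a mitochondrial limit of 10%, cytotoxic (0.16), TRAF5 receptor (0.23) and cytokine (0.10) lists in T cells, matrix in fibroblasts (0.0897) and type I interferon in cycling cells (0.0926) were weaker, the NK cytotoxic list (-0.14) stronger, and the ratio of unnamed cells 4.72. The NK cytotoxic list was at -0.13 and outside the middle range with a pseudocount of 10 CPM. TMM scaling and the reduced total use 1 factor for all genes of a class, so they say little about a place among random lists: under them the NK cytotoxic list (-0.10 and -0.14) and type I interferon in cycling cells (0.168 and 0.1204) and, under TMM scaling, matrix in fibroblasts (0.12) crossed a limit next to which they lay.

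With libraries merged without integration, the share ratio was 0.822 for neutrophils and 1.31 for unnamed cells, the NK cytotoxic list (-0.21) was stronger and cytokines in dendritic cells (0.0799) weaker. A cluster of 215 wild-type and 81 knockout cells with neutrophil genes was left unnamed there, which goes into both share ratios. At resolution 0.4 the ratio of club or secretory cells was 1.32. There the club or secretory cluster (104 and 186 cells) also had the ciliated cell markers Tmem212 and Dynlrb2 among its leading genes, and no cluster was named ciliated. At resolution 1.6 it was 0.860 for aerocyte and 0.694 for general capillary endothelium and 1.57 for unnamed cells. With a minimum of 1000 UMIs the ratio of unnamed cells was 5.77. No value came out for ciliated cells at resolution 0.4 or a mitochondrial limit of 10%, for the germinal centre list with at least 100 UMIs, and for interferon gamma response in nonclassical monocytes after thinning or with at least 100 UMIs. List members with few UMIs, such as Lag3 in T cells (6 wild-type UMIs), have wide intervals.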

Other observations

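Several tests here were chosen after the result was seen: dissociation stress for the clock pattern, cluster shares and depth for the T cell pattern, and, for the interferon pattern, the spread by resampling as part of the rule.

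Some single genes differed alike in many classes. Slc15a2 was lower in B cell-like (0.362), T cell-like (0.414), NK cell-like (0.415, 0.283 to 0.603), alveolar macrophage-like (0.405), interstitial macrophage-like (0.340, 0.271 to 0.425), neutrophil-like (0.492) and endothelium-like cells (0.390, 0.295 to 0.513), and nearer to 1 in gamma delta T cell-like cells (0.842, 0.561 to 1.29). Cdk5rap1 was higher in neutrophil-like (14.1), T cell-like (3.91), classical monocyte-like (4.13, 1.82 to 10.5) and B cell-like cells (2.76). Both are ratios of knockout over wild type with counting intervals. Of the clusters without a name, cluster 31 was led by the cardiac muscle genes Myl7, Tnni3 and Tnnt2 (18 and 37 cells), cluster 30 by Csf1, Ccl3 and Tnf (10 and 48 cells), and cluster 17 by Ctla2a, Gng11 and Emp2 at median depths of 754.5 and 721 UMIs. Cluster 34 had a mixed profile, with its highest marker score for alveolar macrophages (2.131; 9 markers detected) and Cd163l1, Il23r, Pdk4 and Il17a as leading genes, and held 0 of 9006 wild-type cells (at most 0.0410%) and 18 of 12245 knockout cells, at a median of 18696.5 UMIs. Knockout medians were 16251 UMIs in alveolar macrophage-like and 4776 in gamma delta T cell-like cells. Cluster 34 was not told apart from remaining doublets of these 2 classes, so it is not shown to be a separate population.

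Clock and glucocorticoid-responsive genes stood apart in fibroblast-like and endothelium-like cells: beyond Nr1d1, fibroblast-like cells had lower Dbp (0.111, 0.0535 to 0.209), Per3 (0.293) and Tef (0.427) and higher Nfil3 (2.53), Sgk1 (2.22) and Klf9 (1.71). Clock genes whose values had not been seen had median absolute log2 ratios of 0.53 in endothelium-like and 0.87 in fibroblast-like cells, at percentiles 99.93 and 100, and stood high too in mural (99.98), T (99.81), B (99.27) and alveolar macrophage-like cells (97.6), in line with tissue taken at another time of day, although they stood at percentiles 6.61 to 19.74 in interstitial macrophage-like, gamma delta T cell-like, NK cell-like and neutrophil-like cells, and Nr1d2 was lower in fibroblast-like (0.473) but higher in T cell-like (1.503) and B cell-like cells (1.54). Glucocorticoid target genes not seen before stood at 0.47 and 0.77, both at percentile 100, in line with a different glucocorticoid exposure, and at or above the upper limit of the middle range in mural, neutrophil, classical and nonclassical monocyte, cycling, NK, gamma delta T and B cell-like cells, but at -0.35 in interstitial macrophage-like cells (percentile 3.54) and at percentiles 52.77 in dendritic cell-like, 77.12 in alveolar macrophage-like, 89.16 in aerocyte and 89.65 in T cell-like cells. The dissociation and heat shock list stood at 0.16 (percentile 99.9) and 0.28 (percentile 100), but at -0.06 (percentile 18.77) in fibroblast cluster 10. It was above the middle range in mural cell-like cells too. It was below that range in alveolar macrophage-like (-0.25), dendritic cell-like (-0.34), NK cell-like (-0.22), B cell-like (-0.13), cycling cell-like (-0.15) and interstitial macrophage-like cells. In T cell-like, gamma delta T cell-like and classical monocyte-like cells it was inside the range. Stress of dissociation also stays possible in fibroblast-like and endothelium-like cells. All 3 explanations remain open, as does the genotype, which was not tested and goes with the library.

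The interferon gamma response and MHC class I lists were higher in fibroblast-like and endothelium-like cells, and RNA of other cells may contribute. In endothelium-like cells the members' level in the lowest class was 1.234 times their excess (median), which alone would go with free RNA, but pan leukocyte genes were lower (-0.2642), and the excess would need a 31.316% share of another cell class where markers showed at most 0.427% (73.4 times less; 17.3 to 113 by resampling), which argues against RNA of other cells as the whole cause there. In fibroblast-like cells the level was 0.96 times the excess, pan leukocyte genes were higher (0.4602), and the needed share was 8.2% against 1.363% (6.01 times; 2.10 to 8.01), with a range that includes the bound of 5, so RNA of other cells and a real difference cannot be told apart there. The test of the needed share was added after the other tests left the question undecided, with its prediction written before its own result. That prediction asked for a ratio over 5 in both classes. The point values (73.4 and 6.01) met it, but the lower resampling bound in fibroblast-like cells (2.10) did not. Reading each class by itself was not part of the prediction. A difference by genotype stays open in both classes and was not tested.

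The activation and exhaustion list was higher in T cell-like cells (0.91), where another mixture of the clusters could be part of the cause. With both T cell clusters weighted alike the median was 0.4989, lower than the main value but still outside the middle range, so the mixture of these clusters may account for part of the difference but not for all of it. Values also argue against depth (median of 0.9507 after thinning) and against free RNA (level in the lowest class at 0.027 times the excess) as the cause. The cluster test had been run with clusters at resolution 1.6 (0.5472) and was then reworded to the main clusters. At that resolution a cluster of 67 wild-type and 154 knockout cells was named ILC2 and so was left out of the value. Its leading genes included Il1rl1, Areg and Foxp3 and the activation list members Tnfrsf9, Tox and Ctla4. Finer states inside cluster 5 were not compared, and they and the genotype, which was not tested, stay open.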
